A study of Rattus norvegicus with 12 samples.

How the data were processed

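RNA-seq libraries were made from total RNA of rat hepatic progenitor cells, extracted with Trizol and prepared from 1 ug with an Illumina TruSeq RNA kit, per the labels' protocols. The aligner, the quantification tool, the genome build, the annotation and any filter are not given in the sources used here. The authors deposited one table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) on a log2 scale, with 22730 lines and 1 column for each of the 12 libraries. That the deposited values are log2(FPKM + 1) was inferred from the values, because the table does not state its scale: they run from 0 to 16.8 and sum to 38816 to 47619 per library, too few for FPKM, while 2 to the power of the value, minus 1, sums to 447554 to 2085916. A natural log would give sums of 5617965 to 129359570, above those usual for FPKM. If the base were another, every fold would change and the order of values within a gene would not. How FPKM was scaled between libraries is not given, and FPKM is a share of a library, so genes that take much of 1 library lower the values of all others there.

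Of the 22730 lines 346 hold no gene symbol and were left out, and 1835 share their symbol with another line and were kept apart, so counts of genes are counts of lines. Columns were matched to samples by the sample descriptions, and no column was left unused. Gene symbols are as deposited; of the 11860 tested genes 10999 (92.7%) have a symbol in the rat reference annotation GRCr8, which was used for names only, and no coordinates are given because the build of the table is unknown. Paralogues that share reads, such as the Akr1c genes, are uncertain. No counts were at hand, so the depth of the libraries is unknown and no counting interval is given.

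Libraries were grouped by genotype and treatment from their labels. Genes with a mean FPKM of at least 1 over the 12 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), a pseudocount of 1, which understates the change of low genes. A model of 6 group means was fitted to all 12 libraries, which share 1 estimate of the spread, with empirical Bayes moderation along the intensity trend, no block and no further normalization. There were 9 contrasts: TNFα against untreated in each of 3 genotypes, the difference of that response between each knockout label and wild type, and each knockout label against wild type without and with TNFα. P-values are two-sided and adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05. Every adjusted p of a gene is from limma, and every adjusted p of a list is from camera, adjusted over the lists of its contrast. Camera compares a list with all other genes and used a preset inter-gene correlation of 0.01; of its 162 tests 54 passed, and 8 passed with the correlation estimated from the residuals. Because it is relative to other genes, its direction differed from the sign of the list's median or mean in 5 of 18 lists for TNFα in wild type, 4 for Tnfrsf1α-/-, 7 for Tnfrsf1β-/-, 5 and 6 for the differences in response, 5 and 7 for the untreated knockouts and 2 and 5 for the treated ones, in none of them for a list that passed.

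The samples, the tests, the 21 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The lists covered NF-kB feedback and adhesion, chemokines and cytokines, immediate early genes, YAP and TAZ targets, Hippo components, TNF receptor signalling, hepatic progenitor and cholangiocyte markers, hepatocyte genes, mesenchymal and stellate cells, endothelial cells, macrophages and leukocytes, erythroid genes, cell division, interferon, hypoxia and glycolysis, unfolded protein and amino acid stress, heat shock, cholesterol synthesis, p53 targets, mesenchymal transition and TNF-induced apoptosis regulators. Lists with fewer than 5 tested members, the endothelial, macrophage and erythroid ones, were not tested. Genes named are Tnfrsf1a, Tnfrsf1b, Yap1, Wwtr1 and Hnrnpk, the 10 highest and 10 lowest fold changes per contrast among genes past the threshold whose libraries do not overlap, and up to 4 members of each list with the smallest p in that contrast; not every gene the rule allows is printed, and some are not reported here. A few members named beside another contrast, to follow a gene through the groups, were chosen after their values were seen. The 287-gene and 173-gene sets were defined after the data were seen.

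The fit was tested on simulated data drawn from each gene's mean and residual spread, with 100 genes moved 2-fold and 100 moved 8-fold. The moved genes were drawn only from those above a set mean level, so the shares recovered do not cover genes of low level. Of the 8-fold changes 86%, 84% and 88% were called for TNFα in wild type, Tnfrsf1α-/- and Tnfrsf1β-/-, 63% and 68% for the differences in response, 85% and 91% for the untreated knockouts and 88% and 92% for the treated ones. Of the 2-fold changes 16%, 20% and 16%, 0% and 2%, 21% and 20%, and 18% and 14% were called in the same order. Far fewer genes were moved here than passed in the data, which makes the adjustment stricter, so these shares may understate the recovery in the data. A difference in response that did not pass is still taken as weak evidence of none.

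Alternatives were median-ratio scaling, quantile normalization, a pseudocount of 0.1, no filter or a mean FPKM of at least 5, no intensity trend, only the groups of a contrast, the replicate number as a block, an added 2-fold limit, an estimated inter-gene correlation, and each library left out in turn. Comparisons that share wild-type libraries were set beside 20 simulations of unchanged groups. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.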

Results

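RNA from rat hepatic progenitor cells (HPCs), the immature liver cells that can give rise to hepatocytes and bile duct cells, was measured by RNA-seq in 12 libraries. The labels give gestation day 13.5 as the age and divide the libraries into 6 groups of 2: wild type, Tnfrsf1α-/- and Tnfrsf1β-/- cells, each untreated or given tumour necrosis factor alpha (TNFα) for 1 hour. The genes named in these labels encode the TNF receptors TNFR1 and TNFR2. The series title places the work around TNFR2, the RNA-binding protein hnRNPK and the transcriptional co-activator YAP in liver cancer. The comparisons below address how TNFα changed each genotype, whether the change differed between genotypes, and how the genotypes differed with and without TNFα. Levels are log2(FPKM + 1), differences are on that scale, and each group mean is given with its SD over n = 2 libraries. Nothing in the labels says that the libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. The number of reads behind each library is unknown, because the values are already scaled to FPKM.

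The gene for TNFR1, Tnfrsf1a, was not lower in the libraries labelled Tnfrsf1α-/-. Its level was 5.45 and 5.15 in the 2 untreated wild-type libraries, 5.65 and 5.63 in wild type with TNFα, 5.94 and 6.13 in the untreated libraries labelled Tnfrsf1α-/-, 5.65 and 5.95 under that label with TNFα, 5.83 and 5.80 in untreated Tnfrsf1β-/-, and 4.85 and 4.71 in Tnfrsf1β-/- with TNFα. These groups are therefore called libraries labelled Tnfrsf1α-/-, and every direction drawn from them rests on the label. The word "knockout" below means libraries with either knockout label. A transcript level does not show whether a deletion left a transcript without function. The gene for TNFR2, Tnfrsf1b, was listed at 0 in all 4 libraries labelled Tnfrsf1β-/- and also in both untreated wild-type libraries. Without TNFα it therefore does not separate these labels. It was at 2.58 and 2.43 in wild type with TNFα, at 0.03 and 0 in the untreated libraries labelled Tnfrsf1α-/-, and at 0 and 4.09 under that label with TNFα. With TNFα the difference of Tnfrsf1β-/- from wild type did not pass in the main fit (-2.5, limma adjusted p = 0.0649). The name Tnfrsf1β-/- below therefore also rests on the label. A listed 0 can be a failed estimate.

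The libraries did not spread by genotype or treatment alone. The first principal component held 53.1% of the variance and ran from the 4 untreated knockout libraries to the 2 wild-type libraries with TNFα. The second, with 27.1%, set the untreated wild-type and the TNFα-treated Tnfrsf1β-/- libraries apart from the rest. Across the tested genes, which are not independent replicates, Spearman's rho between replicates was 0.961 in wild type, 0.994 in wild type with TNFα, 0.992 under the label Tnfrsf1α-/-, 0.996 in Tnfrsf1β-/-, 0.974 in Tnfrsf1β-/- with TNFα and 0.782 under the label Tnfrsf1α-/- with TNFα. Untreated wild type replicate 1 and TNFα-treated Tnfrsf1β-/- replicate 1 were at 0.983, although they differ in both labels. The pair labelled Tnfrsf1α-/- with TNFα differed by over 2 log2 units in 1231 of 11860 genes. Total FPKM was 447554 to 472935 in the 4 untreated knockout libraries and 1071530 to 2085916 in the other 8.

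**Figure D1:**
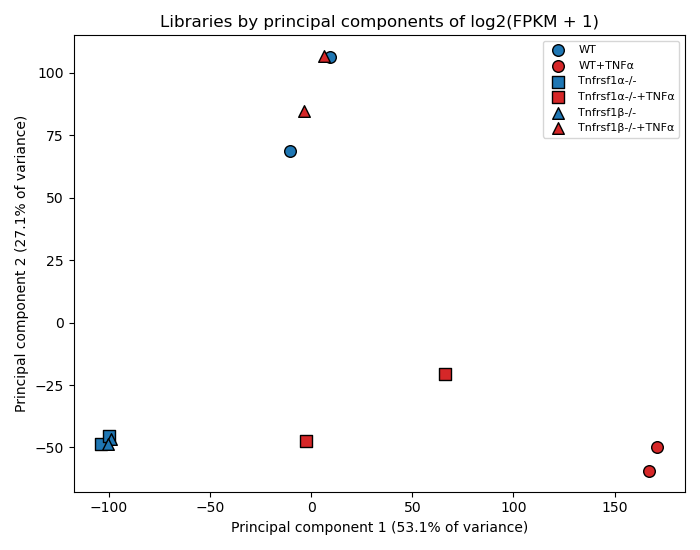
Each point is 1 of the 12 libraries, placed by its first (x axis) and second (y axis) principal component score. Scores are over the tested genes on the log2(FPKM + 1) scale. Colour gives the treatment (blue untreated, red with TNFα) and marker shape the genotype label. The components hold 53.1% and 27.1% of the variance; the 4 untreated knockout libraries lie together and the 2 libraries labelled Tnfrsf1α-/- with TNFα lie apart.

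Marker genes of liver cell types also divided the libraries. The median level of 18 hepatocyte genes was 7.34 and 7.45 in the wild-type libraries with TNFα and at most 0.09 in the other 10. The median of the mesenchymal and stellate cell markers was 0.28 and 0.85 in the same wild-type libraries, against 5.35 to 7.97 in the other 10. Apart from these markers, 287 genes lay over 2 log2 units higher in every treated library of wild type and of the label Tnfrsf1α-/- than in any untreated wild-type or treated Tnfrsf1β-/- library. A further criterion, chosen like the first after the data were seen, found 173 genes over 2 log2 units lower in all 4 untreated knockout libraries than in any other library. These groups of genes are called the 287-gene and the 173-gene set. Because they were chosen on differences between the groups compared below, members change in several of these comparisons by that choice alone. Together they hold 447 genes and 19.8% to 62.2% of total FPKM in 8 libraries, against 2.9% to 3.4% in the untreated knockouts.

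Wild-type cells given TNFα showed hepatocyte genes that untreated wild type lacked. Alb, which encodes serum albumin, was listed at 0 in both untreated libraries and at 10.01 and 9.92 with TNFα. Ahsg, for the plasma glycoprotein fetuin-A, went from 0 in both to 10.43 and 10.48, and Ttr, for the thyroxine carrier transthyretin, from 0 in both to 10.24 and 10.46. Krt18, an epithelial keratin, was at 0 in both untreated libraries and at 9.64 and 9.84 with TNFα. All 18 tested hepatocyte genes rose (18 adjusted over the list alone; camera adjusted p = 2.7e-15, adjusted p = 0.00674 with an estimated correlation). The list has 22 members. The 18 tested had a median near 0 in all other libraries, so they passed the expression filter largely through these treated ones. That all of them rose is therefore in part set by the filter. Of 13 hepatic progenitor and cholangiocyte markers 11 rose (11 adjusted over the list alone, camera adjusted p = 2.1e-06, adjusted p = 0.0225 with an estimated correlation). Among them was Cd24, listed at 0 in both untreated libraries and at 6.17 and 6.05 with TNFα. This list has 20 members. Those at 0 in untreated wild type, such as Krt18 and Cd24, may have passed the filter largely through the treated libraries. The count of 11 may therefore be set in part by the filter as well.

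Of the mesenchymal markers that passed in the same comparison, more fell than rose. Vim, for the intermediate filament vimentin, fell from 10.65 ± 0.11 to 1.28 ± 0.08 (log2 change -9.37, SE 0.36, adjusted p = 6.3e-08). Sparc, a secreted matrix-binding protein, fell from 10.54 ± 0.21 to 0.56 ± 0.40, and Des, for the muscle and stellate cell filament desmin, from 6.16 ± 0.17 to 1.33 ± 0.01. Tagln, a smooth muscle actin-binding protein, rose by 3.28 (SE 0.26). Of 11 mesenchymal and stellate cell markers 8 fell and 2 rose (8 and 2 adjusted over the list alone; adjusted p = 0.00188, adjusted p = 0.242 with an estimated correlation). Tmsb4x, for the actin-sequestering protein thymosin, fell from 13.51 ± 0.53 to 0.49 ± 0.03, and Ceacam6, an adhesion molecule, went from a listed 0 in both libraries to 14.81 and 14.64.

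Genes known to be induced by NF-kB, the main transcription factor below TNF receptors, did not rise as a group in wild type. Cxcl1, a chemokine that attracts neutrophils, fell from 8.26 ± 0.12 to 1.07 ± 0.12 (log2 change -7.20, SE 0.21, adjusted p = 1.3e-08). Ccl2, a monocyte chemokine, fell from 10.16 ± 0.29 to 0.07 ± 0.10, and Zc3h12a, an RNase that limits inflammatory transcripts, from 4.16 ± 0.34 to 0.92 ± 0.01. Cflar, an inhibitor of death receptor signalling, rose from 8.72 ± 0.09 to 10.84 ± 0.01. Of 24 genes of NF-kB feedback and adhesion 3 rose and 9 fell (3 and 9 adjusted over the list alone; adjusted p = 0.0363, adjusted p = 0.469 with an estimated correlation; adjusted p = 0.0535 after median-ratio scaling). Of 17 chemokines and cytokines 2 rose and 9 fell (2 and 9 over the list alone; adjusted p = 0.00188, adjusted p = 0.363 with an estimated correlation). Of 20 interferon-stimulated genes 1 rose and 10 fell (1 and 10 over the list alone; adjusted p = 1.1e-04, adjusted p = 0.469 with an estimated correlation). Isg15, a ubiquitin-like antiviral protein, fell by 3.70 (SE 0.27), and Oas1a, which makes an activator of RNase L, was at 5.06 and 5.0 untreated and listed at 0 in both libraries with TNFα.

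The genes of the series title were followed in the same wild-type comparison. Hnrnpk rose from 6.90 ± 0.49 to 10.87 ± 0.77 (log2 change 3.97, SE 0.62, adjusted p = 0.001). Yap1, which encodes YAP, was at 4.78 and 2.30 untreated and at 4.48 ± 0.07 with TNFα (log2 difference 0.93, SE 0.65, adjusted p = 0.268; adjusted p = 0.00149 without wild type replicate 1). Wwtr1, for its paralogue TAZ, fell by 0.77 (SE 0.23, adjusted p = 0.0242; 0.0551 with only the groups compared, and 0.109, 0.0752 and 0.104 without untreated replicate 1 or either treated wild-type replicate). Of 21 YAP and TAZ targets 11 rose and 4 fell (11 and 5 adjusted over the list alone), and the shift of the list against other genes did not pass (adjusted p = 0.341, adjusted p = 0.82 with an estimated correlation). The receptor kinase Axl rose from 6.64 ± 0.61 to 12.81 ± 0.05, the cofactor gene Ankrd1 from 3.17 ± 1.15 to 11.04 ± 0.00, and the angiomotin family member Amotl2 from 5.69 ± 0.48 to 10.67 ± 0.00. Hnrnpk, Axl, Ankrd1 and Amotl2 belong to the 287-gene set, which holds 6 of the 21 targets. Without the genes of both sets 2 of 12 targets rose and 4 fell (camera adjusted p = 0.119). Their median was -1.21, against 1.13 with the set genes. The 287-gene set was chosen to be higher in these treated libraries than in untreated wild type. Leaving it out therefore lowers the count and the median in part by that choice. The same 2 treated libraries are the ones with hepatocyte genes and few mesenchymal transcripts.

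Other groups were counted in the same wild-type comparison. Of 22 cell division genes 10 rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 0.0356, adjusted p = 0.469 with an estimated correlation). Tyms, the thymidylate synthase gene, rose by 7.11 (SE 0.17), and Ccnb1, a mitotic cyclin, by 6.36 (SE 0.20). Of the 22 genes 8, among them these 2, belong to the 287-gene set. Without the genes of both sets 1 of 13 rose and 2 fell, and the list did not pass (camera adjusted p = 0.573). Here too the choice of the 287-gene set brings the fall about in part. Of 20 cholesterol synthesis genes 11 rose and 1 fell (11 and 1 over the list alone; adjusted p = 0.0373, adjusted p = 0.808 with an estimated correlation), with Insig1, a sterol sensor, up by 6.33 (SE 0.24) and Fdps, farnesyl diphosphate synthase, up by 4.74 (SE 0.27), both of the 287-gene set. Of 22 immediate early genes 6 rose and 4 fell (7 and 5 over the list alone; adjusted p = 0.742; 5 and 8 after median-ratio scaling and 6 and 7 after quantile normalization), with the phosphatase gene Dusp1 up by 6.72 (SE 0.28) and the AP-1 gene Junb up by 5.12 (SE 0.23), both of the 287-gene set.

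In all, 5601 of 11860 genes changed with TNFα in wild type by limma at an adjusted p under 0.05, 3786 higher and 1815 lower. The median of all genes moved by 0.32 log2, so that 67.6% of the calls were higher; after median-ratio scaling and after quantile normalization 49.2% and 45.6% were. With 1 library left out the count was 3520 and 3618 without the treated wild-type replicates 1 and 2, and up to 7646 without another; it was 3875 without the 4 untreated knockout libraries and 7644 without both treated libraries labelled Tnfrsf1α-/-, settings added after the data were seen. Library make-up moved too. Ribosomal protein genes held 14.8% and 20.8% of total FPKM untreated and 7.0% and 7.4% with TNFα, mitochondrial genes 4.6% and 2.7% and then 1.1% and 1.0%, and the 10 highest genes 16% and 15.2% and then 24.1% and 27.5%.

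In the libraries labelled Tnfrsf1α-/-, where Tnfrsf1a itself was not lower, 594 of the 1163 genes that rose with TNFα also rose in wild type, against 371 for independent lists. Another 204 fell in both, against 136, and 291 went opposite ways. Without the 447 genes of the 2 sets 538 genes rose under this label. The fall from 1163 exceeds the size of the sets, so genes outside them also lost their call in that fit. Hnrnpk rose from 7.94 ± 0.14 to 11.66 ± 1.47 (log2 change 3.72, SE 0.62, adjusted p = 0.00431), a call lost after quantile normalization (1.77, adjusted p = 0.0825) and with only the groups compared (adjusted p = 0.184). Yap1 was at 6.06 ± 0.09 and 5.71 ± 0.13 (adjusted p = 0.713). Wwtr1 was at 5.57 ± 0.14 and 4.89 ± 0.15, a difference that did not pass (adjusted p = 0.0739) but did after median-ratio scaling (-0.65, adjusted p = 0.0275) and quantile normalization (-1.12, adjusted p = 0.00214), and without the treated replicate 1 (adjusted p = 0.03). Of 21 YAP and TAZ targets 10 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 2.3e-04, adjusted p = 0.292 with an estimated correlation). Ankrd1 rose from 1.63 ± 0.02 to 13.41 ± 0.05, and Nt5e, the ectonucleotidase also called CD73, from 0.63 ± 0.10 to 11.80 ± 0.01. Igfbp3, a carrier of insulin-like growth factors, was listed at 0 in both untreated libraries and at 11.10 and 10.79 with TNFα. The 287-gene and 173-gene sets hold 9 of the 21 targets. Without the genes of these sets 1 of 12 targets rose and 1 fell, with a median of -0.84 against 1.07 with them. The list then did not pass (camera adjusted p = 0.906). The 173-gene set was chosen to be lower in these untreated libraries than in the treated ones, so this fall is in part built in.

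Of the immediate early and NF-kB genes that passed under this label, more fell than rose. Fos, an AP-1 subunit that growth signals induce within minutes, fell from 5.90 ± 0.02 to 1.13 ± 0.24 (log2 change -4.78, SE 0.23, adjusted p = 7e-07), while Junb and Dusp1 rose by 3.25 and 3.70. Of 22 immediate early genes 8 fell and 2 rose (10 and 2 adjusted over the list alone; adjusted p = 0.00297, adjusted p = 0.276 with an estimated correlation). Bcl3, an atypical IkB protein, fell by 2.99 (SE 0.30), and Cflar rose from 4.79 ± 0.11 to 11.38 ± 0.29. Of 24 NF-kB genes 7 fell and 1 rose (9 and 1 over the list alone; adjusted p = 0.00587, adjusted p = 0.319 with an estimated correlation). Of 17 chemokines and cytokines 4 fell and 1 rose (10 and 1 over the list alone; adjusted p = 0.0106, adjusted p = 0.372 with an estimated correlation). Of 20 interferon-stimulated genes 8 fell (13 over the list alone; adjusted p = 2.3e-04, adjusted p = 0.433 with an estimated correlation), with Ifit2, an antiviral RNA-binding protein, down from 3.21 ± 0.14 to 0.64 ± 0.80, a call lost with only the groups compared (adjusted p = 0.133).

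Cell division and mesenchymal transition genes were followed in the same libraries. Tyms rose by 6.12 (SE 0.17) and Ccnb1 by 4.71 (SE 0.20), and of 22 cell division genes 13 rose (14 adjusted over the list alone; adjusted p = 1.8e-08, adjusted p = 0.134 with an estimated correlation), with 9 of the 22 in the sets. The adhesion gene Cdh2, of the 173-gene set, rose by 5.99 (SE 0.18) and the repressor gene Zeb1 by 5.93 (SE 0.34). Of 16 epithelial to mesenchymal transition genes 5 rose (5 higher and 1 lower over the list alone; adjusted p = 8.0e-04, adjusted p = 0.134 with an estimated correlation), with 3 of the 16 in the sets. Of 13 progenitor and cholangiocyte markers 4 rose (4 higher and 1 lower over the list alone; adjusted p = 0.00452, adjusted p = 0.134 with an estimated correlation), among them Sox9, a biliary transcription factor, from 0.27 ± 0.06 to 9.53 ± 0.19, and Krt7, a bile duct keratin, from 7.87 ± 0.17 to 14.87 ± 0.33. All 4 belong to the 287-gene or 173-gene sets. The median level of the 18 hepatocyte genes was 0.07 and 0.09 in the treated libraries. Of 20 hypoxia and glycolysis genes 4 rose (4 over the list alone; adjusted p = 0.00877, adjusted p = 0.737 with an estimated correlation; 3 higher, 4 lower and adjusted p = 0.756 after quantile normalization), with the stress gene Ndrg1, of the 287-gene set, up by 7.25 (SE 0.52). Of 20 cholesterol genes 4 rose (5 over the list alone; adjusted p = 0.0349, adjusted p = 0.828 with an estimated correlation), with Mvd, of the mevalonate pathway and the 287-gene set, up by 8.04 (SE 0.27). Without the genes of both sets 0 of 16 rose, and the list did not pass (camera adjusted p = 0.906). The sets were chosen on high values in these treated libraries, so this loss is in part built in.

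Here 2052 genes changed, 1163 higher and 889 lower (56.7% higher, 47.5% after median-ratio scaling and 34.8% after quantile normalization). The pair of treated libraries was the least alike of the 6, and the count was 7001 without the treated replicate 1, 750 and 851 without the untreated replicates 1 and 2, and 1310 without either untreated Tnfrsf1β-/- library. It was 3789 after quantile normalization and 570 with only these groups. Mitochondrial genes held 6.0% and 5.4% of total FPKM untreated and 2.0% and 2.5% with TNFα, ribosomal protein genes 9.3% and 9.7% and then 6.5% and 9.9%, and the 10 highest genes 7.9% and 7.8% and then 16.4% and 16.2%.

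With TNFα in Tnfrsf1β-/- cells, the immediate early and Hippo lists were called lower, but not with an estimated correlation (adjusted p = 0.409 and 0.925). The NF-kB list did not pass in the main fit. Hnrnpk was at 6.75 ± 0.03 untreated and 6.57 ± 0.33 with TNFα (log2 difference -0.18, SE 0.62, adjusted p = 0.843). Wwtr1 fell from 5.82 ± 0.01 to 4.12 ± 0.30 (adjusted p = 0.00057). Yap1 fell from 6.01 ± 0.09 to 3.98 ± 0.57 (adjusted p = 0.0253) and Tnfrsf1a by 1.04 (SE 0.19, adjusted p = 0.0018), calls lost after median-ratio scaling at -1.28 (adjusted p = 0.0886) and -0.28 (adjusted p = 0.242). The Yap1 call was also lost without either untreated Tnfrsf1β-/- replicate (adjusted p = 0.0804 and 0.0972) or without the treated replicate 2 (0.15). The list of 20 Hippo pathway components holds kinases that restrain YAP beside Yap1, Wwtr1, Hnrnpk and the Tead genes. It is therefore not a count of the restraining cascade alone. Of the 20 components 16 fell and 1 rose (16 and 1 adjusted over the list alone; adjusted p = 0.0171, adjusted p = 0.925 with an estimated correlation; 15 and 2 after median-ratio scaling), with the kinase gene Stk4 at -1.62 (SE 0.24). Of 21 YAP and TAZ targets 5 rose and 10 fell (5 and 11 over the list alone; adjusted p = 0.834, with the median of -0.90 and the mean of -0.21 on the other side of 0 from the test). After median-ratio scaling 5 rose and 5 fell, with a median of -0.12 (adjusted p = 0.987). After quantile normalization 7 rose and 10 fell, with a median of -1.17. Igfbp3 was listed at 0 in both untreated libraries and at 10.42 and 10.57 with TNFα, Nt5e rose by 8.10 (SE 0.17), and Ccdc80, a matrix protein, fell by 3.46 (SE 0.21). Cyr61, a secreted target of YAP, was at 9.42 and 9.36 untreated and listed at 0 in both treated libraries.

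Fos fell from 6.14 ± 0.02 to 0.25 ± 0.36 in the same Tnfrsf1β-/- comparison, Nr4a1, an orphan nuclear receptor, changed by -4.81 (SE 0.33), and Btg2, an antiproliferative gene, by -3.96 (SE 0.23). Of 22 immediate early genes 16 fell (16 adjusted over the list alone; adjusted p = 0.00445, adjusted p = 0.409 with an estimated correlation). Tnfaip3, which encodes the NF-kB inhibitor A20, fell from 5.24 ± 0.02 to 1.67 ± 0.42. Of 24 NF-kB genes 19 fell and 1, Cflar of the 173-gene set, rose (19 and 1 over the list alone; adjusted p = 0.0681). Without the genes of the 2 sets 19 of 23 fell and 0 rose, and the list passed (camera adjusted p = 0.0197). The 173-gene set was chosen to be higher here with TNFα, so leaving out Cflar removes a rise by that choice. After median-ratio scaling 11 fell and 2 rose (adjusted p = 0.0798). The list passed after quantile normalization (adjusted p = 0.0014). Of 13 progenitor and cholangiocyte markers 4 rose, all in the 173-gene set, led by Krt7 with a rise of 6.05 (SE 0.25) and Sox9 with 5.96 (SE 0.26; 4 over the list alone; adjusted p = 0.00891, adjusted p = 0.348 with an estimated correlation; adjusted p = 0.0955 after median-ratio scaling). Of 20 hypoxia and glycolysis genes 5 rose and 1 fell (4 and 1 over the list alone; adjusted p = 0.0171, adjusted p = 0.925 with an estimated correlation; 2 higher, 4 lower and adjusted p = 0.833 after quantile normalization). The glycolytic genes Tpi1 and Gapdh rose by 2.64 (SE 0.60) and 1.61 (SE 0.39); after quantile normalization the Tpi1 call was lost (1.28, adjusted p = 0.0503) and Gapdh turned to -0.73.

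In Tnfrsf1β-/- cells 7172 genes changed with TNFα, 2086 higher and 5086 lower. The median of all genes moved by -0.66 log2, and the share of higher calls, 29.1%, was 49.9% after median-ratio scaling and 44.8% after quantile normalization. Leaving out 1 library gave 4979 to 8759 genes. The treated and untreated libraries also differed in make-up. Ribosomal protein genes held 8.7% and 8.4% of total FPKM untreated and 19.4% and 21.8% with TNFα, and mitochondrial genes 5.4% in both and then 2.2% and 1.6%. Genes at an FPKM of 1 or more numbered 11279 and 11275 untreated and 10168 and 9780 with TNFα. The 10 highest genes held 8.0% and 7.8% and then 13.7% and 16.2%.

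The change with TNFα was then compared between genotypes by a test of the difference itself. The rise of Hnrnpk in wild type was not matched in Tnfrsf1β-/-, with a difference in response of -4.15 (SE 0.88, adjusted p = 0.00342). Between wild type and the libraries labelled Tnfrsf1α-/- it was -0.25 (SE 0.88, adjusted p = 0.84). Yap1 differed by -2.96 in Tnfrsf1β-/- (SE 0.92, adjusted p = 0.0208), a call lost after median-ratio scaling (-1.78, adjusted p = 0.0898) and without any of 4 single libraries, both treated wild-type ones and replicate 2 of each Tnfrsf1β-/- group (adjusted p = 0.0572 to 0.0758). Yap1 in the libraries labelled Tnfrsf1α-/- differed by -1.29 (adjusted p = 0.297; -2.53, adjusted p = 0.00334, without untreated wild type replicate 1). Wwtr1 differed by -0.93 in Tnfrsf1β-/- (adjusted p = 0.0329) but by 0.27 after median-ratio scaling and -0.58 (adjusted p = 0.0753) after quantile normalization, and the call was lost (adjusted p = 0.0522 to 0.102) without untreated wild type replicate 2, either treated wild-type library, any untreated knockout library or treated Tnfrsf1β-/- replicate 2. Tnfrsf1a differed by -1.37 (adjusted p = 0.0021) but by -0.14 (adjusted p = 0.678) after median-ratio scaling. Hnrnpk belongs to the 287-gene set, and the wild-type side of each difference rests on the 2 treated libraries with hepatocyte genes. The knockout side rests in turn on the untreated knockout libraries, which lay apart from the rest. In Tnfrsf1β-/- Yap1 was 2.46 above wild type untreated but differed by -0.49 with TNFα (limma adjusted p = 0.555).

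A difference in response above 0 can be a larger rise or a smaller fall than in wild type. Of 21 YAP and TAZ targets, 8 had a difference above 0 and 3 below 0 under the label Tnfrsf1α-/- (8 and 3 adjusted over the list alone; adjusted p = 0.0133, adjusted p = 0.637 with an estimated correlation; adjusted p = 0.0728 after quantile normalization). In Tnfrsf1β-/- 6 were above 0 and 9 below (6 and 9 over the list alone; adjusted p = 0.626, the test pointing up and the median of -1.07 down; 7 and 6 after median-ratio scaling). Without the genes of the 2 sets 4 of 12 targets were above 0 and 1 below under the label Tnfrsf1α-/-, which did not pass (camera adjusted p = 0.0641). In Tnfrsf1β-/- 3 were then above 0 and 3 below (camera adjusted p = 0.415). Amotl2 differed by -6.96 (SE 0.32) in Tnfrsf1β-/-, and Nt5e by 10.04 (SE 0.24) under the label Tnfrsf1α-/- and 6.97 (SE 0.24) under Tnfrsf1β-/-. All 18 hepatocyte genes, which rose in wild type, had differences below 0 in both (18 and 18 over the list alone; adjusted p = 1.6e-17 and 5.4e-10; adjusted p = 0.0046 and 0.0214 with an estimated correlation). Vim differed by 10.3 and 9.0 (SE 0.50 each), Sparc by 9.35 (SE 0.85) and Des by 6.44 (SE 0.46) under the label Tnfrsf1α-/-. Of 11 mesenchymal markers 4 had a difference above 0 and 2 below 0 under the label Tnfrsf1α-/- (4 and 2 over the list alone; adjusted p = 0.0133, adjusted p = 0.344 with an estimated correlation; 0.0936 after quantile normalization), and 4 were above 0 and 1 below under Tnfrsf1β-/- (4 and 1 over the list alone; adjusted p = 0.0297, adjusted p = 0.625 with an estimated correlation; 0.0692 after median-ratio scaling and 0.247 after quantile normalization). In each case all 4 markers above 0 had fallen in wild type.

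Of 16 mesenchymal transition genes 9 had a difference in response above 0 and 1 below 0 under the label Tnfrsf1α-/- (9 and 1 adjusted over the list alone; adjusted p = 1.8e-04, adjusted p = 0.0862 with an estimated correlation). Of these 9, 4 fell in wild type and did not pass under the label. In Tnfrsf1β-/- 4 were above 0 and 2 below (4 and 2 over the list alone; adjusted p = 0.148). Fos differed by -5.82 (SE 0.33) under the label Tnfrsf1α-/- and by -6.93 (SE 0.33) under Tnfrsf1β-/-. Cxcl1, which fell in wild type, differed by 5.52 (SE 0.30) under the label Tnfrsf1α-/-. In Tnfrsf1β-/- the responses of Dusp1, Junb and Tyms, all of the 287-gene set, differed by -8.28 (SE 0.39), -7.47 (SE 0.33) and -7.77 (SE 0.24). In all, 4127 genes differed in response between the label Tnfrsf1α-/- and wild type, 1522 up and 2605 down, and 7654 between Tnfrsf1β-/- and wild type, 2048 up and 5606 down. The medians of all genes were -0.44 and -1.11, and the shares of upward calls, 36.9% and 26.8%, were 51.6% and 49.7% after median-ratio scaling and 48.0% and 47.5% after quantile normalization. The first count was 7125 without the treated replicate 1 labelled Tnfrsf1α-/-, 2392 and 2676 without the treated wild-type replicates 1 and 2, 2429 and 2543 without the untreated replicates 1 and 2 labelled Tnfrsf1α-/-, and 2751 with only its groups.

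**Figure D2:**
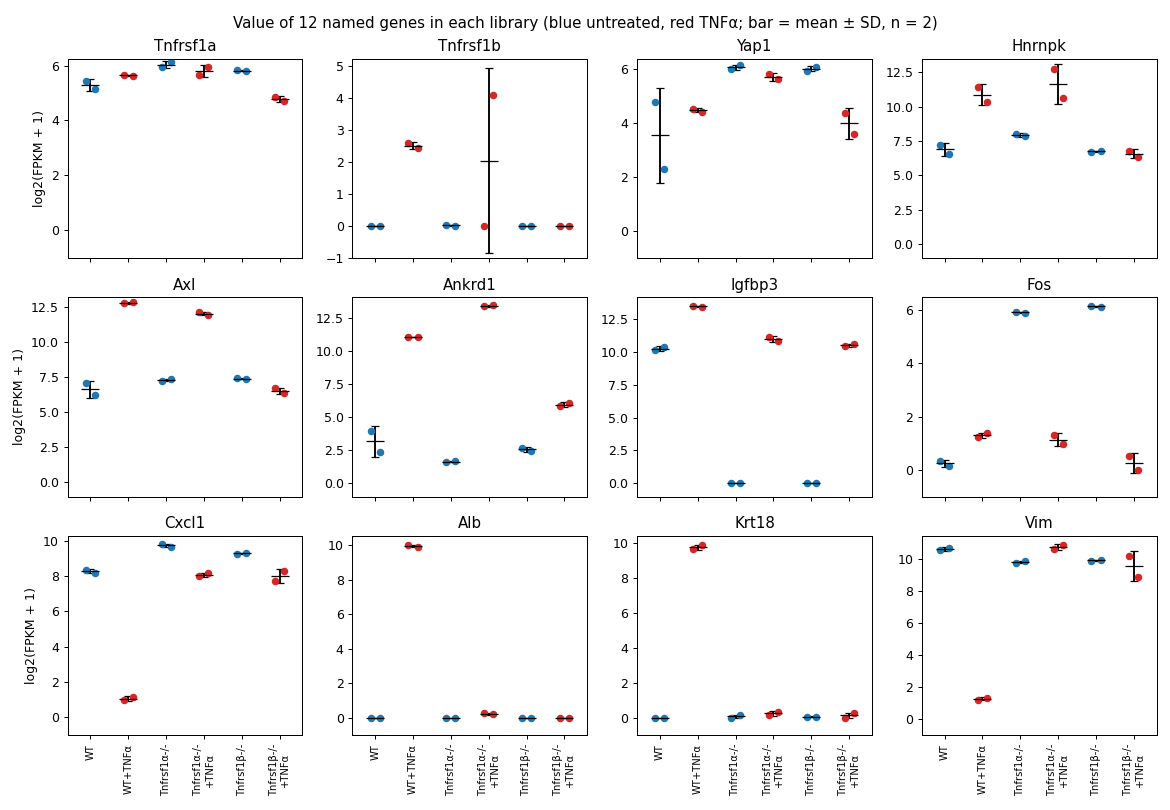
Level of 12 genes (y axis, log2(FPKM + 1)) in the 6 groups (x axis), with 1 point per library, blue untreated and red with TNFα, and the mean ± SD over n = 2 libraries. Hnrnpk is at 10.87 ± 0.77 in treated wild type, 11.66 ± 1.47 under the label Tnfrsf1α-/- with TNFα and 6.57 ± 0.33 in treated Tnfrsf1β-/-, Alb is listed above 1 only in the 2 treated wild-type libraries, and Tnfrsf1a stays between 4.71 and 6.13 in every library.

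Untreated libraries of either knockout label differed from untreated wild type in many of the same genes, and these 4 libraries are the ones with the low total FPKM. Yap1 was higher by 2.52 (SE 0.65, adjusted p = 0.0113) in the libraries labelled Tnfrsf1α-/- and by 2.46 (SE 0.65, adjusted p = 0.0124) in Tnfrsf1β-/-, where the wild-type pair was at 4.78 and 2.30; with only the groups compared neither passed (adjusted p = 0.083 and 0.0963), nor without either replicate of the knockout group (adjusted p = 0.0505 to 0.0615). Wwtr1 was higher by 1.2 and 1.45 (SE 0.23 each), and Hnrnpk differed by 1.04 (adjusted p = 0.189) and -0.15 (adjusted p = 0.875), neither of which passed. Hnrnpk did pass under the label Tnfrsf1α-/- at 2.28 (adjusted p = 0.0241) after quantile normalization, with only the groups compared (adjusted p = 0.0435) and without either treated library labelled Tnfrsf1α-/- (0.0317 and 0.0313). Tnfrsf1a was higher by 0.74 (adjusted p = 0.00996) and 0.52 (adjusted p = 0.0433), and by 0.19 (adjusted p = 0.439) and -0.01 (adjusted p = 0.98) after median-ratio scaling. The first Tnfrsf1a call was lost without wild type replicate 2 or replicate 2 labelled Tnfrsf1α-/- (adjusted p = 0.0566 and 0.0759), and the second without wild type replicate 2, either treated wild-type library or any untreated knockout library (adjusted p = 0.054 to 0.197). Of 20 Hippo components 15 were higher and 1 lower under the label Tnfrsf1α-/-, and 16 higher under Tnfrsf1β-/- (15 and 1, and 16, adjusted over the list alone; adjusted p = 0.0111 and 0.00953; adjusted p = 0.767 and 0.786 with an estimated correlation). The kinase genes Taok1 and Lats1 were higher by 3.41 (SE 0.47) and 2.65 (SE 0.41) under the label Tnfrsf1α-/-, and by 3.29 and 2.59 under Tnfrsf1β-/-.

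Fos was at 0.33 and 0.16 in untreated wild type, 5.90 ± 0.02 under the label Tnfrsf1α-/- and 6.14 ± 0.02 in Tnfrsf1β-/-, and Fosb, its close relative, was higher by 3.93 and 4.51 (SE 0.32 each). Of 22 immediate early genes 16 and 15 were higher and 1 and 1 lower (16 and 15 higher, 1 and 1 lower adjusted over the list alone; adjusted p = 0.0107 and 0.00338; adjusted p = 0.575 and 0.383 with an estimated correlation). Tnfaip3 was higher by 3.14 and 3.53 (SE 0.42 each) and the cytokine gene Il6, at 2.20 and 2.52 under the label Tnfrsf1α-/-, was at 0.17 and 0 in wild type. Of 24 NF-kB genes 15 and 18 were higher and 1 and 1 lower (17 and 19 higher, 1 and 1 lower over the list alone; adjusted p = 0.0358 and 0.0264; adjusted p = 0.575 and 0.746 with an estimated correlation).

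Igfbp3 was listed at 0 in all 4 untreated knockout libraries, against 10.12 and 10.36 in untreated wild type. Nt5e changed by -8.55 and -8.59 (SE 0.17 each), and Sox9 and Krt7 were lower in both, with changes of -5.23 and -5.78 under the label Tnfrsf1α-/- and -5.46 and -5.99 under Tnfrsf1β-/-. Of 13 progenitor and cholangiocyte markers 4 and 4 were lower (4 and 4 adjusted over the list alone; adjusted p = 0.0107 and 0.0103; adjusted p = 0.427 and 0.383 with an estimated correlation; 0.0772 and 0.0635 after median-ratio scaling), all 4 in the 173-gene set. Of 22 cell division genes 4 were higher and 10 lower under the label Tnfrsf1α-/- (4 and 11 over the list alone; adjusted p = 0.0107, adjusted p = 0.575 with an estimated correlation; 3 and 15 after median-ratio scaling; 0.254 after quantile normalization). Top2a, the topoisomerase of dividing cells and a member of the 173-gene set, was at -5.64 (SE 0.27). Without the genes of both sets 4 of 13 were higher and 3 lower under the label Tnfrsf1α-/-, and the list did not pass (camera adjusted p = 0.145). The 173-gene set was chosen to be lower in these libraries, which brings this loss about in part. In Tnfrsf1β-/- 4 of the 22 were higher and 4 lower, with a median of -0.07 (4 and 3 over the list alone; adjusted p = 0.225). There the split was 4 and 9 after median-ratio scaling and 10 and 5 after quantile normalization.

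By limma 6370 genes differed from untreated wild type under the label Tnfrsf1α-/- (4350 higher, 2020 lower) and 6456 under Tnfrsf1β-/- (4377 higher, 2079 lower). The medians of all genes were 0.48 and 0.47, and the shares of higher calls, 68.3% and 67.8%, were 52.0% and 52.5% after median-ratio scaling and 54.1% and 54.0% after quantile normalization. The first count was 4179 without the replicate 1 labelled Tnfrsf1α-/-, and the second 4292 without the wild-type replicate 2 and 4198 without the Tnfrsf1β-/- replicate 2. Of these calls 3896 were higher and 1834 lower in both, against 1605 and 354 for independent lists, and 0 went opposite ways. The fold changes had Pearson's r = 0.98 across genes, against 0.50 simulated for unchanged groups that share these wild-type libraries, and a covariance of 2.32 against 0.11 simulated. Part of the excess may come from the shared controls, since a split would leave 1 control library in each part.

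With TNFα, the genotypes differed from wild type in the hepatocyte and mesenchymal genes above. All 18 hepatocyte genes were lower in both (18 and 18 adjusted over the list alone; adjusted p = 1.3e-19 under the label Tnfrsf1α-/- and 3.0e-14 under Tnfrsf1β-/-; adjusted p = 0.00335 and 0.00819 with an estimated correlation). Of 13 progenitor and cholangiocyte markers 9 and 11 were lower (9 and 11 over the list alone; adjusted p = 7.4e-06 and 4.6e-06; adjusted p = 0.0285 and 0.026 with an estimated correlation). Vim was higher by 9.49 and 8.30 (SE 0.36 each), Sparc by 10.26 and 9.45 (SE 0.60 each), and Krt18 changed by -9.49 and -9.62 (SE 0.18 each). Of 11 mesenchymal markers 5 and 7 were higher and 2 and 2 lower (7 and 7 higher over the list alone; adjusted p = 0.0407 and 0.003; adjusted p = 0.378 and 0.275 with an estimated correlation). Cxcl1 was higher by 6.99 and 6.92 (SE 0.21 each), the growth factor gene Csf1 by 5.67 (SE 0.47) under the label Tnfrsf1α-/-, and Isg15 and Irf7, of the interferon system, by 3.99 and 5.36 under Tnfrsf1β-/-. Of 17 chemokines and cytokines 8 and 9 were higher and 0 and 2 lower (9 and 9 higher over the list alone; adjusted p = 0.00191 and 0.0016; adjusted p = 0.369 and 0.338 with an estimated correlation). Of 20 interferon-stimulated genes 9 and 10 were higher and 0 and 2 lower (9 and 10 higher over the list alone; adjusted p = 0.00156 and 1.9e-04; adjusted p = 0.636 and 0.5 with an estimated correlation).

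Hnrnpk was lower in treated Tnfrsf1β-/- than in treated wild type by a log2 change of -4.30 (SE 0.62, adjusted p = 0.00057), and differed by 0.79 (adjusted p = 0.32) under the label Tnfrsf1α-/- (1.83, adjusted p = 0.00674, without treated replicate 2 of that label). Yap1 differed by -0.49 (adjusted p = 0.555) in Tnfrsf1β-/- and by 1.23 (adjusted p = 0.151) under the label Tnfrsf1α-/-, where it passed with only the groups compared (adjusted p = 0.0388) and without either untreated wild-type replicate (0.00746 and 0.00738). Wwtr1 was higher by 1.29 (SE 0.23, adjusted p = 0.00227) under the label Tnfrsf1α-/- and differed by 0.52 (adjusted p = 0.0918) in Tnfrsf1β-/-, which passed after median-ratio scaling (1.2, adjusted p = 0.00039) and quantile normalization (1.06, adjusted p = 0.00139). Tnfrsf1a was lower in Tnfrsf1β-/- by a change of -0.86 (adjusted p = 0.00512), or -0.15 (adjusted p = 0.53) after median-ratio scaling and -0.18 (adjusted p = 0.394) after quantile normalization. Of 21 YAP and TAZ targets 4 were higher and 12 lower in Tnfrsf1β-/- (5 and 12 adjusted over the list alone; adjusted p = 0.217; 7 and 11, adjusted p = 0.0424, after median-ratio scaling; 6 and 11, adjusted p = 0.054, after quantile normalization), and 9 higher and 4 lower under the label Tnfrsf1α-/- (9 and 5 over the list alone; adjusted p = 0.289). The 287-gene set, chosen to be lower in treated Tnfrsf1β-/- than in treated wild type, holds 6 of these 21 targets. Without the genes of both sets 4 of 12 targets were higher and 3 lower in Tnfrsf1β-/- (camera adjusted p = 0.254). Their median was 1.12, against -2.67 with the set genes. Under the label Tnfrsf1α-/- 7 were then higher and 1 lower (camera adjusted p = 0.0431). Axl and Amotl2, of the 287-gene set, changed by -6.25 (SE 0.26) and -5.39 (SE 0.23) in Tnfrsf1β-/-. Of 20 Hippo components 12 were higher and 1 lower under the label Tnfrsf1α-/- (12 and 1 over the list alone; adjusted p = 0.00956, adjusted p = 0.705 with an estimated correlation). In Tnfrsf1β-/- 2 were higher and 3 lower, with a median of -0.13 (1 and 2 over the list alone; adjusted p = 0.408), and 7 and 3 after either other scaling.

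Of 24 NF-kB genes 11 were higher and 1 lower under the label Tnfrsf1α-/- and 8 higher and 4 lower in Tnfrsf1β-/- (11 and 1, and 8 and 5, adjusted over the list alone; adjusted p = 0.0107 and 0.0211; adjusted p = 0.378 and 0.453 with an estimated correlation; the latter 12 and 2 after median-ratio scaling), with Zc3h12a at 3.05 (SE 0.23) under the label Tnfrsf1α-/-. Of 16 mesenchymal transition genes 13 were higher and 1 lower under the label Tnfrsf1α-/- (14 and 1 over the list alone; adjusted p = 0.00185, adjusted p = 0.127 with an estimated correlation); Snai2, a transition-driving repressor, was at 1.32 and 2.67 there and listed at 0 in both treated wild-type libraries. In Tnfrsf1β-/- 3 of these genes were higher and 4 lower (3 and 4 over the list alone; adjusted p = 0.399). The split was 5 and 4 after median-ratio scaling. There 12 of 22 cell division genes were lower and 2 higher (12 and 2 over the list alone; adjusted p = 0.0182, adjusted p = 0.453 with an estimated correlation; 11 and 4 after median-ratio scaling), with Tyms at -7.34 and Ccnb1 at -6.71, both of the 287-gene set. Without the genes of both sets 3 of 13 were lower and 2 higher, and the list did not pass (camera adjusted p = 0.762). The choice of the 287-gene set brings this loss about in part. In the same cells 11 of 18 unfolded protein and amino acid stress genes were lower (11 over the list alone; adjusted p = 0.0261, adjusted p = 0.692 with an estimated correlation; 0.054 after quantile normalization), with Phgdh, of serine synthesis and the 287-gene set, at -4.22 (SE 0.22). Of 20 cholesterol genes 11 were lower and 1 higher (12 and 1 over the list alone; adjusted p = 0.0261, adjusted p = 0.705 with an estimated correlation), with Insig1 at -6.86 (SE 0.24). Under the label Tnfrsf1α-/- none of these 3 lists passed: 4 cell division genes were higher and 10 lower (4 and 10 over the list alone; adjusted p = 0.171), 1 and 4 stress genes (1 and 4 over the list alone; adjusted p = 0.375), and 3 and 4 cholesterol genes (3 and 4 over the list alone; adjusted p = 0.37).

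With TNFα 5356 genes differed from wild type under the label Tnfrsf1α-/- (2697 higher, 2659 lower) and 6046 in Tnfrsf1β-/- (1743 higher, 4303 lower; 28.8% higher, 54.9% after median-ratio scaling and 53% after quantile normalization, with a median of all genes of -0.41). The first count was 2111 with only these groups, 3504 and 3081 without the treated wild-type replicates 1 and 2, and 3637 without the untreated knockout libraries; the second was 3937 without the treated wild-type replicate 1. Of these calls 984 were higher and 2011 lower in both (396 and 965 for independent lists) and 232 went opposite ways; the covariance of the fold changes was 2.62 against 0.11 simulated, and Pearson's r across genes 0.72 against 0.50. The differences in response had r = 0.82 (0.50 simulated) and a covariance of 4.32 (0.22 simulated), with 1240 higher and 2488 lower in both, against 263 and 1231. In these simulations the shared wild-type libraries differed by noise alone. A shift of the treated wild-type libraries would enter the comparisons of both knockout labels. The excess over the simulations therefore does not show a likeness between the knockouts. The responses themselves share no libraries. Across genes r was 0.41 between wild type and the label Tnfrsf1α-/-, -0.03 between wild type and Tnfrsf1β-/-, and 0.56 between the knockout labels. Both knockout responses are measured from the untreated knockout libraries, which lay together (Spearman's rho 0.974 to 0.981 between the labels). A shift common to those libraries would enter both responses, so 0.56 does not show a like response to TNFα.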

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

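All of the tests that weigh explanations here were chosen after the results they bear on had been seen. What is listed first are results whose change with TNFα differed between a knockout label and wild type in a test of that difference, the limma interaction term.

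Under the label Tnfrsf1α-/-, whose Tnfrsf1a level was not lower, 4127 genes differed in response from wild type. Among the genes named, the difference in log2 response was 10.3 for Vim, 6.44 for Des, 9.35 for Sparc, 10.04 for Nt5e, -5.82 for Fos and 5.52 for Cxcl1. In Tnfrsf1β-/- 7654 genes differed. The difference was -1.37 for Tnfrsf1a, -2.96 for Yap1, -0.93 for Wwtr1, -4.15 for Hnrnpk, -6.96 for Amotl2, 6.97 for Nt5e, -8.28 for Dusp1, -7.47 for Junb, -6.93 for Fos, -7.77 for Tyms and 9.0 for Vim. The Tnfrsf1a, Yap1 and Wwtr1 calls were lost, or the last turned, after median-ratio scaling. Of these genes Hnrnpk, Amotl2, Dusp1, Junb and Tyms belong to the 287-gene set weighed next. Vim, Sparc, Des and Cxcl1 move with the treated wild-type libraries weighed after it. Nt5e belongs to the 173-gene set, low in the untreated knockout libraries weighed last. The differences of Fos, and of Yap1 in Tnfrsf1β-/-, rest largely on those libraries too. Untreated, Fos was above wild type by 5.66 under the label Tnfrsf1α-/- and 5.89 in Tnfrsf1β-/-, and Yap1 by 2.46 in Tnfrsf1β-/-.

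The 287 genes high in the treated libraries of wild type and of the label Tnfrsf1α-/- and low in untreated wild type and treated Tnfrsf1β-/- include Hnrnpk, Axl, Amotl2 and Ankrd1. The reverse split of the same 8 libraries gave 20 genes. No other split of 4 against 4 (70 in all) gave more than that, though many of them part replicates. A hepatocyte population common to the 4 high libraries is argued against by the 18 hepatocyte genes, whose median reached 0.09 at most under the label Tnfrsf1α-/- against 7.34 and 7.45 in treated wild type; another shared population stays open. A TNF response stays open: 3 of 24 NF-kB genes rose in wild type and 9 fell, between the bounds set for and against it. Values of part of the gene names on another scale or from another source may be a candidate explanation, since 23.3% of the set's symbols start with A against 7.1% of the genes outside it (67 of 287 and 818 of 11573, Fisher's exact p = 1.3e-17, two-sided), a letter picked after the table of all initials was seen. The letter O was nearly as high: 6.9% of the tested symbols starting with O (7 of 102) were in the set. For A it was 7.6%, and for any other letter at most 3.6%. A biological source of the set was not excluded.

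Treated wild-type libraries held hepatocyte transcripts and few mesenchymal ones. Scaling between libraries is argued against, since the hepatocyte genes' median change was 6.11 or more under both other scalings. A change of the same cells within 1 hour is argued against by 34 of 527 genes at 8 or more in both untreated wild-type libraries that were at least 6 log2 units lower in both treated ones, a loss that needs a half-life of at most 10 minutes with no synthesis; 3 such genes were found under the label Tnfrsf1α-/- and 0 in treated Tnfrsf1β-/-. Another cell population under this label is left as a candidate explanation. All 18 hepatocyte genes that passed the filter were higher, a count the filter sets in part. Alb was near 10 (10.01 and 9.92) and 8 of 11 mesenchymal markers were lower. If so, the wild-type response, and each comparison that uses these 2 libraries, could compare cell populations as well as treatments. Of 13 tested progenitor and cholangiocyte markers 11 were also higher in these 2 libraries, a count the filter may also set in part. The values therefore do not settle which libraries are closer to the labelled progenitor cells.

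The 4 untreated knockout libraries lay apart from the other 8, whatever their label. Every change with TNFα under a knockout label is measured from these libraries. A few genes taking most of the signal is argued against, since without the 447 genes and after rescaling 5763 genes still differed from wild type under the untreated label Tnfrsf1α-/- and 5784 in untreated Tnfrsf1β-/-. Receptor loss acting alike with and without TNFα is argued against for Tnfrsf1β-/-, since 2.7% of its untreated calls lay at least 0.5 times as far from untreated wild type, the same way, in the treated libraries (15% against treated wild type), but it stays open under the label Tnfrsf1α-/-, where 58.8% did (79.5% and 39.5% in the single libraries, 40.7% against treated wild type). A separate preparation or processing of these 4 libraries cannot be told apart from a change of untreated cells with a knockout label, since the labels give no batch and the split follows the groups. The lowest total FPKM of the other 8 libraries was 2.27 times the highest of these 4, which a difference in processing could give.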

How the results depend on the processing

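The settings that leave out whole groups of libraries, or the 447 genes of the 2 sets, were chosen after seeing the data; the others were planned. Of 81 values that the 9 counts of changed genes took under planned settings that kept all libraries of the fit or only those compared, 77 lay within 1.5 times the main count. With only the groups of a contrast, TNFα under the label Tnfrsf1α-/- gave 570 genes, its difference from wild type 2751 and the treated libraries of that label against wild type 2111, with fewer libraries to estimate the spread. Quantile normalization gave 3789 for TNFα under the label Tnfrsf1α-/-; the cause was not tested. Without the 447 genes that comparison gave 1206, a fall that the choice of the 2 sets on this difference brings about in part. The list tests that passed numbered 56 against 54, but they were not all the same tests. Calls lost included the progenitor markers with TNFα under the label Tnfrsf1α-/- and in Tnfrsf1β-/- (camera adjusted p = 0.697 and 0.45). Among those gained were chemokines and cytokines for the difference in response in Tnfrsf1β-/- (camera adjusted p = 0.0357). Lost calls of YAP and TAZ targets, cell division and cholesterol genes are given above. Because the sets were chosen on differences between the groups compared, such losses and gains are in part set by that choice. With an estimated correlation 8 of the 162 list tests passed; the cause was not tested.

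Leaving out 1 library, with the lone library of that group assumed to vary like the rest, moved the count for TNFα in wild type between 3520 and 7646, under the label Tnfrsf1α-/- between 750 and 7001, in Tnfrsf1β-/- between 4979 and 8759, the difference in response of the label Tnfrsf1α-/- between 2392 and 7125 and of Tnfrsf1β-/- between 6216 and 9287, the untreated label Tnfrsf1α-/- between 4179 and 8128, untreated Tnfrsf1β-/- between 4198 and 8174, the treated label Tnfrsf1α-/- between 3081 and 7716 and treated Tnfrsf1β-/- between 3937 and 7816. The highest values came without a treated library labelled Tnfrsf1α-/-, whose pair has the widest spread. Values over 1.5 times below the count came without libraries of the groups compared or, for TNFα under the label Tnfrsf1α-/-, without an untreated Tnfrsf1β-/- library.

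The replicate number as a block gave 5896, 2675, 7316, 4570, 7902, 6589, 6586, 5717 and 6360 genes in the order of the contrasts above. By the rule used, the numbers did not pair the libraries: over 15 pairs of groups, deviations of same-numbered libraries correlated at -0.17 to 0.24 across genes. Of these pairs 9 were over 0.1, among them all 6 among untreated wild type and the 3 treated groups (0.15 to 0.24), but the rule used asked for every pair. With the block the Tnfrsf1a call in untreated Tnfrsf1β-/- was lost (adjusted p = 0.0522). Of the 158 gene comparisons followed, 3077 of 3154 alternative values kept direction and side of the threshold, 52 lost and 22 gained a call. There were 3 reversals: Gapdh with TNFα in Tnfrsf1β-/- at -0.73 after quantile normalization, and, after median-ratio scaling, the Wwtr1 difference in response in Tnfrsf1β-/- at 0.27 and Tnfrsf1a in untreated Tnfrsf1β-/- at -0.01. The cause was not tested. Depth is unknown, so how far it limits the low genes is not known.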

Other observations

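Amino acid stress and cholesterol genes were counted with TNFα in each genotype. In wild type 11 of 18 unfolded protein and amino acid stress genes rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.149), in the libraries labelled Tnfrsf1α-/- 3 rose (3 over the list alone; adjusted p = 0.786) and in Tnfrsf1β-/- 2 rose and 8 fell (2 and 8 over the list alone; adjusted p = 0.892; 4 and 3 after median-ratio scaling). The amino acid synthesis gene Asns rose by 3.13 in wild type, and Hsp90b1, a chaperone of the endoplasmic reticulum, rose by 1.35, 4.96 and 3.11 in the 3 genotypes. For the difference in response 1 gene of this list was higher and 11 lower in Tnfrsf1β-/- (1 and 11 over the list alone; adjusted p = 0.33; 4 and 7 after median-ratio scaling), as were 1 and 15 of 20 cholesterol synthesis genes (1 and 15 over the list alone; adjusted p = 0.123). Neither list passed, except after quantile normalization (adjusted p = 0.0398 for each).

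Other lists gave counts without a shift that passed. Of 14 p53 targets 4 rose and 4 fell with TNFα in wild type (4 and 4 adjusted over the list alone; adjusted p = 0.484), with Gdf15, a stress cytokine, up by 5.89 and Phlda3, an inhibitor of Akt, at -8.45. Of 14 lines for 13 heat shock genes, with the chaperone gene Hspa8 on 2 lines that both rose, 6 rose and 2 fell (6 and 3 over the list alone; adjusted p = 0.742; 4 and 6 after median-ratio scaling, 1 and 5 after quantile normalization), with Hspb1, a small chaperone, at -5.35. Of 25 TNF receptor signalling components 8 rose and 3 fell in wild type (8 and 3 over the list alone; adjusted p = 0.986; 3 and 5 after median-ratio scaling), and in Tnfrsf1β-/- 3 rose and 18 fell (3 and 18 over the list alone; adjusted p = 0.226; 5 and 8 after median-ratio scaling), with the kinase gene Ripk1 at -2.28. Of 11 TNF-induced and apoptosis regulators 4 rose and 2 fell in wild type (5 and 2 over the list alone; adjusted p = 0.791; 3 and 4 after median-ratio scaling), and the survival gene Bcl2l1 rose by 8.50 under the label Tnfrsf1α-/- and by 7.14 in Tnfrsf1β-/-. Of 4 endothelial markers tested in wild type Esam rose by 4.21 and Egfl7 was at -2.75; of the 2 macrophage markers Cd14 differed by -0.96 and Cd68 by 0.07, neither of which passed; and the only erythroid gene tested, Hbe1, was at -2.13. Genes of this paragraph and the one before it were in part chosen after their values were seen.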
